A study of Dunaliella viridis with 39 samples.

How the data were processed

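The labels describe 39 RNA samples of Dunaliella viridis strain dumsii grown under continuous light of 125 µmol photons per m2 per s at 23.5 °C. Per the labels' protocols, ribosomal RNA was removed from total RNA with a plant leaf depletion kit, strand-specific libraries were made, and single-end reads of 125 bp were sequenced in 2 runs. The 4 treatment cultures were set up in 450 ml of medium and duplicated, and the experiment was carried out 3 times for 3 biological replicates. How the duplicate cultures entered the libraries is not given in the sources used here. The inoculum label states that it grew on nitrate and started the treatments of the same replicate.

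The authors deposited a table of read counts and a table of transcripts-per-million (TPM) values, each with a column per library and 18495 loci. The submitters' processing notes name FastQC, STAR, RSEM and edgeR 3.4.0, with no roles or order. The genome build, annotation, strand setting and any filter are not given in the sources used here. The deposited counts are whole numbers of reads, and the deposited TPM values sum to the same fixed total in every library. A depleted total RNA library also holds transcripts without a poly(A) tail, and 1 locus, Locus_10041, was the most abundant in every library, so the loci with most counts weigh on any scaling to a total. Reads from near-identical loci could be split between them in ways that cannot be judged from the tables. Every column matched a sample title, and 0 columns were left without a sample.

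Groups, times and replicate numbers were taken from the sample labels. The counts were analysed with edgeR 4.0.16 in R 4.3.3. Loci were kept by filterByExpr on the groups, which left 17569 loci and removed 926 that held 0.0235% of the counts. Library sizes were scaled with TMM factors, which ranged from 0.617 to 2.16. All 39 libraries entered a single quasi-likelihood fit with a mean per group, so that all groups share an estimate of the spread, and contrasts of groups were tested for the 19 comparisons with Benjamini-Hochberg adjustment over loci at a threshold of 0.05. Standard errors were derived from the log2 fold change and the quasi-likelihood F value and are approximate. Intervals are at the 95% level. Levels are CPM on TMM-scaled libraries, given as mean ± SD of 3 libraries, and log2 CPM used a prior count of 2. Counting intervals cover counting error only.

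Loci were named by a rule fixed before the data were examined. Where IDs carry no names it takes, for each comparison at a given time, each time course and the transfer, the 2 loci with the largest positive and the 2 with the largest negative log2 fold change among called loci with a mean of at least 10 CPM over both groups and no overlap between the groups. A locus may then be followed through other media and times. At glutamine against nitrate only lower loci met the rule at 3 h and only higher loci at 27 h, and at glutamine against glutamate only lower loci at 3 h. Gene lists on nitrogen uptake, photosynthesis, lipid and carbon metabolism had been fixed beforehand and were not tested, because IDs could not be matched to names.

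Within each group no pair of libraries agreed to within sampling noise: the lowest chi-square per degree of freedom of a pair was 5.63 over loci with at least 10 counts in the pair. The labels make a replicate number a shared repeat of the experiment, so the numbers pair the libraries. Deviations from the group means correlated at a mean of 0.0964 between libraries of the same number and -0.0477 between different numbers, and 49.6% of the 234 same-number pairs were above 0.1. All libraries of replicate 1 were in run 1, all of replicate 3 in run 2, and those of replicate 2 in either.

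The alternatives were DESeq2-style size factors (RLE) in edgeR, no filter on low counts, DESeq2 1.42.0, replicate as a block, run as a covariate, a fit of the compared libraries alone, limma 3.58.1 with a mean-variance trend on log2(TPM + 1) or log2(TPM + 0.1), and leaving out each library. A fit within a run was made where it held every group compared and more than 1 library of at least 1 of them. Counts without the 3 libraries that stand apart and within a run, and alternatives for the starvation index, were added after the data were seen. The starvation index, the set of 31 loci and their tests were also defined after the data were seen. Single values per library were compared with exact permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. The fits were tested on simulated counts with 100 loci changed 2-fold and 100 changed 4-fold in each of 2 comparisons.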

Results

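RNA was sequenced from Dunaliella viridis strain dumsii, a unicellular green alga of salt water. Cells from a nitrate-grown inoculum were moved into 4 media, which held 5 mM nitrate, 5 mM glutamine, 5 mM glutamate or no added nitrogen, and were sampled 3, 27 and 51 h later. The inoculum itself was also sequenced, which gave 13 groups of 3 libraries and 39 libraries in all. The whole experiment was repeated 3 times per the labels, so the libraries of a group came from separate cultures and the p-values rest on biological replicates. The main fit ignored the pairing of libraries by replicate number, which entered as a block in an alternative fit. Total counts per library ranged from 3342102 to 41114965 with a median of 10192407, and 17569 of the 18495 loci had enough counts to be tested. The files name loci by number and do not pair these IDs with gene names, so the responses are described as sets of loci, and single loci are given by their ID with the level in counts-per-million (CPM).

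Time without usable nitrogen was the main axis of variation. The first principal component of log2 CPM held 36.03% of the variance and set the no nitrogen and glutamate libraries of 27 and 51 h apart from all other libraries. Replicates of a group correlated at Pearson's r of 0.875 to 0.986 across loci, which are not independent of each other. There were 3 libraries that stood apart from their groups. In nitrate 3 h replicate 2 and glutamate 51 h replicate 3 the 10 most abundant loci took 18.2% and 17.5% of the counts, against 40.4% to 59.6% in the other 37 libraries. No nitrogen 51 h replicate 1 had counts in 15777 loci, against at least 17719 in every other library, and lay far from the others on the second component, which held 13.2% of the variance.

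The comparison of no nitrogen with nitrate asked how cells responded to the loss of their nitrogen source. At 27 h without nitrogen 3541 loci were higher and 3358 lower, together 39.3% of those tested, and 2341 of the higher and 1399 of the lower loci differed at least 2-fold. The loci that rose had a median of 3.24 CPM in nitrate and 7.75 CPM without nitrogen, those that fell 24.2 and 12.7 CPM, and all tested loci 5.63 and 6.17 CPM, where the choice of the loci by this same difference draws the sets apart. Locus_568 fell from 61.3 ± 10.7 CPM in nitrate to 0.223 ± 0.133 CPM without nitrogen (SD, n = 3), a log2 fold change of -8.03 (SE 0.45, edgeR adjusted p = 3.24e-16). Locus_1065 fell from 412 ± 29.3 to 6.20 ± 1.17 CPM (log2 fold change -6.05, SE 0.26, edgeR adjusted p = 3.79e-19). Locus_3569 rose from 0.379 ± 0.165 to 20.2 ± 5.52 CPM (log2 fold change 5.82, SE 0.38, edgeR adjusted p = 1.70e-14), and Locus_11359 rose from 0.665 ± 0.257 to 32.9 ± 3.30 CPM (log2 fold change 5.72, SE 0.47, edgeR adjusted p = 4.47e-12). Within sequencing run 1 alone, with fewer libraries, 4164 loci were called at 27 h (1733 higher and 2431 lower). On log2(TPM + 1) values limma called 1571 higher and 321 lower, with the median of all loci moved from 0.09 to 0.33.

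At 51 h the response to missing nitrogen had a similar extent, with 3671 loci higher and 3622 lower than in nitrate. Of the 3541 loci that rose by 27 h, 2447 were called higher and 13 lower at 51 h, where 739.9 and 730.0 would be called in lists that were independent. Of the 3358 loci that fell by 27 h, 2639 were called lower and 1 higher, against 692 and 702 for independent lists. The libraries of the 2 times are separate, but those of a replicate number come from the same repeat of the experiment. The 2 lists are therefore not fully independent. Locus_1065 stood at 1387 ± 211 CPM in nitrate and at 4.72 ± 1.21 CPM without nitrogen (n = 3; log2 fold change -8.30, SE 0.29, edgeR adjusted p = 3.42e-22), and Locus_16559 at 185 ± 74.7 and 0.688 ± 0.279 CPM (-8.40, SE 0.45, edgeR adjusted p = 6.15e-17). At 27 h Locus_16559 had been at 0.366 CPM in nitrate and 0.702 CPM without nitrogen, so its difference at 51 h reflects a later rise in nitrate. By fitted change, the largest rises among loci that met the naming rule were Locus_253, from 0.884 ± 0.251 to 87.9 ± 24.9 CPM (6.68, SE 0.42, edgeR adjusted p = 6.14e-15), and Locus_2857, from 0.828 ± 0.580 to 42.2 ± 7.48 CPM (5.87, SE 0.39, edgeR adjusted p = 1.90e-14). Within run 2 there were 6921 calls, and limma on log2(TPM + 1) gave 1405 higher and 746 lower.

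At 3 h no difference between no nitrogen and nitrate was called by edgeR (0 loci, with 622 at an unadjusted p under 0.05), and DESeq2 called 1 locus. With replicate as a block edgeR also called 1 locus, and it called 3 without nitrate 3 h replicate 1, 1 without nitrate 3 h replicate 3 and 1 without no nitrogen 3 h replicate 2. Of the loci that rose later, by 27 h, 65.6% were nominally higher without nitrogen at 3 h, with a median log2 fold change of 0.11, and of those that fell later 20.01% were, with a median of -0.16. Without no nitrogen 3 h replicate 1 the medians were -0.03 and -0.08, and 45.6% and 31.9% were nominally higher. That fit kept nitrate 3 h replicate 1, which comes from the same repeat. The starvation index described further on was -1.70, -2.49 and -2.17 in no nitrogen 3 h replicates 1, 2 and 3. In the nitrate 3 h libraries it was -2.09, -2.46 and -2.49 in the same order. It was thus higher without nitrogen in replicates 1 and 3 and not in replicate 2. The 95% interval of the fold change lay within 2-fold for 68.2% of loci. In simulated counts for this comparison edgeR recovered 51% of loci changed 2-fold and 86% of those changed 4-fold.

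**Figure D1:**
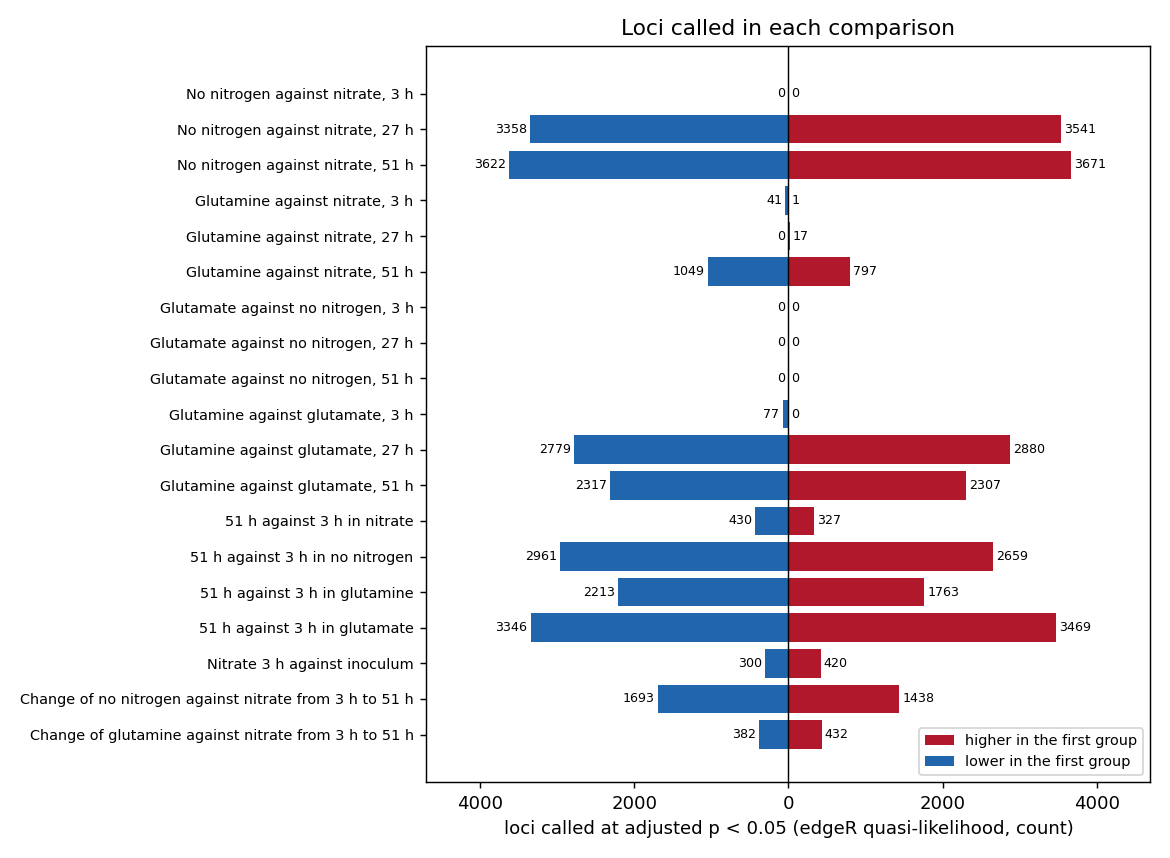
Number of loci called by edgeR at an adjusted p under 0.05 in each of the 19 comparisons, with loci higher in the group named first to the right and loci lower to the left. The bars are longest where cells without usable nitrogen were compared with nitrate at 27 and 51 h (3541 and 3671 loci higher), and glutamate against no nitrogen has 0 calls at each time.

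Per the labels, glutamate served as the control for starvation beside an amino acid that is stable and not used. Glutamate and no nitrogen were not told apart at any of the 3 times. By edgeR 0 loci were called at 3, 27 and 51 h, with 419, 520 and 503 at an unadjusted p under 0.05, and DESeq2 also called 0 at each time. The 95% interval of the fold change lay within 2-fold for 70.0%, 69.4% and 66.8% of the loci at these times. Loci of the nitrogen response followed the same pattern in both media: Locus_1065 fell to 6.64 ± 0.625 CPM in glutamate at 27 h against 6.20 ± 1.17 CPM without nitrogen (n = 3), and Locus_253 stood at 26.4 ± 4.94 against 25.8 ± 2.90 CPM. In simulated counts for the 27 h comparison edgeR recovered 35% of loci changed 2-fold and 83% of loci changed 4-fold, so 2-fold differences would often have been missed. Leaving out no nitrogen 27 h replicate 2 gave 1 call at 27 h.

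Glutamine was set against nitrate to ask how cells fed through this amino acid differ from cells fed an inorganic source. At 3 h the difference went almost wholly downward, with 41 loci lower in glutamine and 1 higher, and 36 of the lower loci differed at least 2-fold. Locus_363 was at 5.38 ± 0.345 CPM in glutamine and 790.2 ± 307 CPM in nitrate (n = 3; log2 fold change -7.20, SE 0.32, edgeR adjusted p = 4.90e-19). Locus_1093 was at 3.75 ± 0.826 against 189 ± 12.2 CPM (-5.68, SE 0.22, edgeR adjusted p = 5.52e-21). Within run 1 there were 27 calls, all lower in glutamine, and a fit of these 6 libraries alone gave 20. Without the 3 libraries that stood apart edgeR called 31 loci, and limma on log2(TPM + 1) called 22, all lower in glutamine.

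At 27 h few loci separated glutamine from nitrate, and the direction was the opposite: 17 loci were higher in glutamine and 0 lower. Locus_9995 was at 26.3 ± 6.83 CPM in glutamine and 3.02 ± 1.27 CPM in nitrate (n = 3; log2 fold change 3.08, SE 0.47, edgeR adjusted p = 3.48e-04), and Locus_55 at 639.8 ± 83.9 and 176 ± 50.1 CPM (1.86, SE 0.25, edgeR adjusted p = 6.33e-05). The count varied with the libraries and the method used. It was 10 without glutamine 27 h replicate 1, 11 without glutamine replicate 3, 10 without nitrate 27 h replicate 1 and 8 without nitrate replicate 2, while DESeq2 called 33 loci and limma on log2(TPM + 1) called 1, under which Locus_55 did not pass. Within run 1, with 1 glutamine and 2 nitrate libraries, and within run 2, with 2 and 1, edgeR called 1 locus each, where the lone library is assumed to vary like those of other groups. Locus_9995 did not pass within run 1, nor Locus_55 within either run.

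By 51 h glutamine-fed cells had moved away from nitrate-fed cells, with 797 loci higher and 1049 lower. The change followed that of cells without nitrogen. Of the loci that had risen by 27 h without nitrogen, 658 were higher in glutamine than in nitrate at 51 h and 9 lower, where independent lists would give 161 and 211. Of the loci that had fallen, 895 were lower and 1 higher, where independent lists would give 200.5 and 152. The size was smaller: the risen loci had a median log2 fold change of 0.41 in glutamine and 1.06 without nitrogen at 51 h, and the fallen loci -0.40 and -0.87. Locus_12170 rose to 80.2 ± 17.4 CPM against 1.21 ± 0.506 CPM in nitrate (n = 3; log2 fold change 6.12, SE 0.34, edgeR adjusted p = 3.68e-16), and Locus_11359 to 32.7 ± 4.89 against 0.553 ± 0.130 CPM (5.78, SE 0.47, edgeR adjusted p = 1.17e-11). Locus_16559 was at 1.26 ± 0.370 against 185 ± 74.7 CPM (-7.11, SE 0.42, edgeR adjusted p = 3.37e-15), and Locus_1115 at 1.60 ± 0.808 against 55.9 ± 7.25 CPM (-5.39, SE 0.52, edgeR adjusted p = 7.24e-10). At 27 h Locus_16559 had been at 0.648 CPM in glutamine and 0.366 CPM in nitrate. Its difference at 51 h thus reflects a later rise in nitrate and not a fall in glutamine. Within run 2 the count was 1115 (477 higher and 638 lower). A fit of these 6 libraries alone gave 799 higher and 653 lower, and limma on log2(TPM + 1) gave 99 higher and 81 lower.

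A nitrogen starvation index summed these sets in each library, as the mean log2 CPM of the loci that rose without nitrogen minus that of the loci that fell, with the loci chosen at 27 h for the libraries of other times and at 51 h for the libraries of 27 h. At 51 h it was -2.55 ± 0.16 in nitrate, -1.64 ± 0.29 in glutamine, -0.59 ± 0.30 without nitrogen and -0.46 ± 0.13 in glutamate (SD, n = 3). All 3 glutamine libraries lay between the nitrate and the no nitrogen libraries. The difference of glutamine from nitrate was 0.91 at 51 h, 0.98 within run 1 and 0.87 within run 2, and the exact permutation test of 3 against 3 libraries gave p = 0.1 (two-sided), the smallest p it allows. At 27 h the index of glutamine was -2.31 ± 0.13 against -2.56 ± 0.10 in nitrate (exact permutation p = 0.1), a difference of 0.18 within run 1 and 0.30 within run 2. At 3 h it was -2.12 ± 0.40 without nitrogen and -2.34 ± 0.22 in nitrate (exact permutation p = 0.7), a difference of 0.18 within run 1 and 0.31 within run 2. These permutation tests ignore the pairing by replicate number. Paired in that way, the difference of glutamine from nitrate was 0.25 ± 0.06 at 27 h and 0.91 ± 0.13 at 51 h (SD, n = 3).

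**Figure D2:**
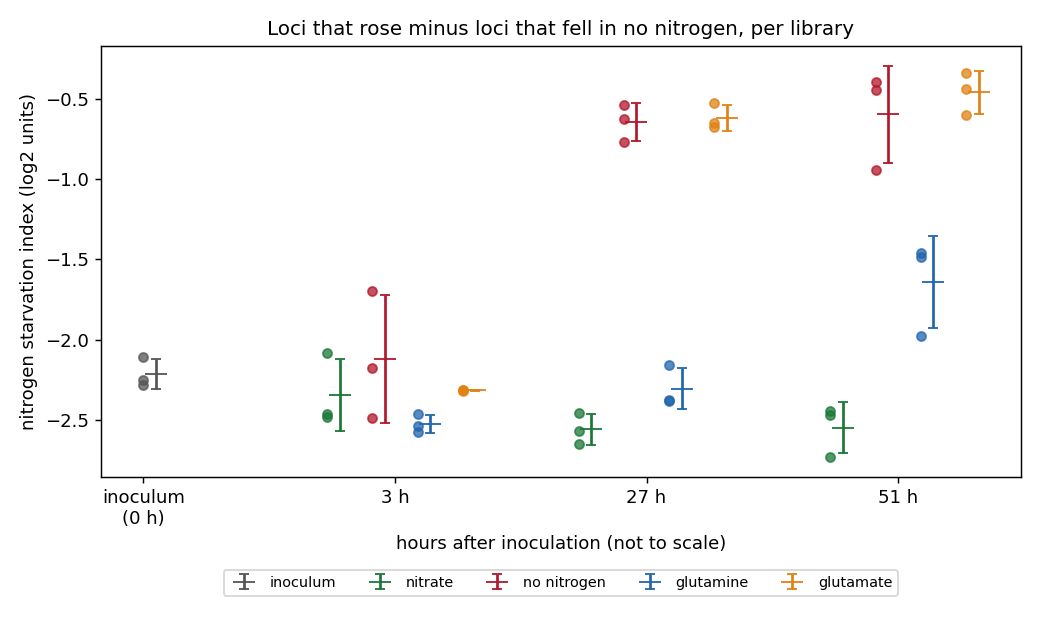
Nitrogen starvation index (vertical axis, log2 units) of each library by time and medium, with points for libraries and bars for the mean and SD of 3. The glutamine libraries lie at -2.31 ± 0.13 at 27 h and at -1.64 ± 0.29 at 51 h, between nitrate (-2.55 ± 0.16) and no nitrogen (-0.59 ± 0.30) at the later time. The loci were chosen at 51 h for the 27 h libraries and at 27 h for all others. Levels at 27 h are therefore not on the same scale as those at other times.

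Glutamine and glutamate, 2 amino acids at the same concentration, were compared directly. At 3 h, 77 loci were lower in glutamine and 0 higher. Locus_363 was at 5.38 ± 0.345 CPM in glutamine and 1333 ± 499 CPM in glutamate (n = 3; log2 fold change -7.95, SE 0.34, edgeR adjusted p = 6.99e-20). Locus_9995 had 2 counts over the 3 glutamine libraries and 1078 over the 3 glutamate libraries, a ratio of 508 with a 95% exact counting interval of 140.2 to 4196. There were 31 loci lower in glutamine than in both nitrate and glutamate, where independent lists would share 0.180 and groups simulated without differences shared 0 in each of 10 simulations. Both lists use the same 3 glutamine libraries, which are too few to split, so the lists are not independent. The simulations drew each locus separately, without deviations shared across a library. They therefore cannot show what overlap such deviations of the glutamine libraries would give. A fit of these 6 libraries alone gave 37 calls, and limma on log2(TPM + 1) gave 20.

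These 31 loci were followed through the other media and times. Their mean log2 CPM was 4.78 ± 0.09 in the inoculum (SD, n = 3) and 2.29 ± 0.09 in glutamine at 3 h, against 5.03 ± 0.19 in nitrate, 5.33 ± 0.16 without nitrogen and 5.40 ± 0.27 in glutamate. At 27 h it was 5.38 ± 0.02 in glutamine and 4.51 ± 0.10 in nitrate, with 12 of the 31 loci called higher in glutamine and 0 lower. It was also above nitrate at 27 h without nitrogen (5.13 ± 0.08, with 15 loci called higher and 7 lower) and in glutamate (5.11 ± 0.04), and glutamine against glutamate had 10 loci higher and 8 lower. At 51 h it was 4.27 ± 0.09 in glutamine and 4.81 ± 0.20 in nitrate, with 15 loci called lower and 10 higher, and 5.04 ± 0.11 in glutamate, with 14 lower in glutamine and 2 higher. Locus_363 went from 5.38 ± 0.345 CPM at 3 h to 1256 ± 191 CPM at 27 h and 116 ± 10.3 CPM at 51 h in glutamine, while it stayed between 517 ± 82.8 and 790.2 ± 307 CPM in nitrate (n = 3). The exact permutation test of the set's mean between glutamine and nitrate gave p = 0.1 at each of the 3 times (two-sided, the smallest p possible), and at 3 h it is not independent of how the set was chosen.

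**Figure D3:**
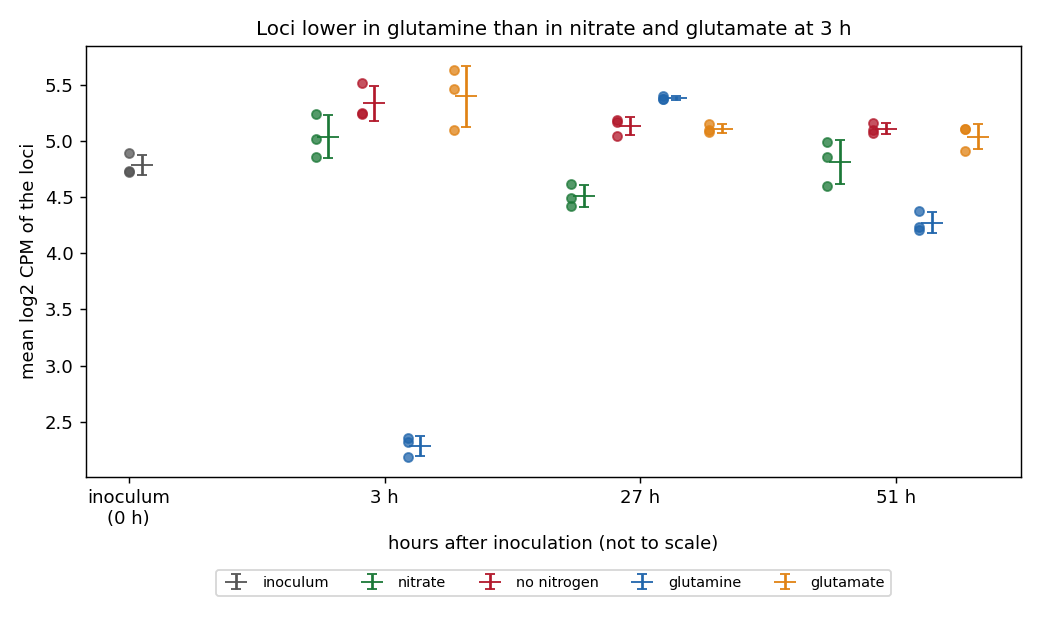
Mean log2 CPM (vertical axis) of the 31 loci lower in glutamine than in both nitrate and glutamate at 3 h, per library by time and medium, with points for libraries and bars for the mean and SD of 3. The glutamine libraries lie at 2.29 ± 0.09 at 3 h, at 5.38 ± 0.02 at 27 h and at 4.27 ± 0.09 at 51 h.

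At 27 h glutamine and glutamate differed in 5659 loci, 2880 higher and 2779 lower in glutamine. Locus_568 was at 54.0 ± 10.04 CPM in glutamine and 0.269 ± 0.106 CPM in glutamate (n = 3; log2 fold change 7.64, SE 0.46, edgeR adjusted p = 3.30e-15), and Locus_1065 at 262 ± 42.6 and 6.64 ± 0.625 CPM (5.31, SE 0.26, edgeR adjusted p = 1.49e-17). Locus_253 was at 1.25 ± 0.601 against 26.4 ± 4.94 CPM (-4.45, SE 0.39, edgeR adjusted p = 3.78e-11), and Locus_11491 at 1.20 ± 1.15 against 22.4 ± 4.15 CPM (-4.38, SE 0.40, edgeR adjusted p = 9.35e-11). Within run 1 edgeR called 1507 loci higher and 714 lower at 27 h and within run 2 it called 1527 higher and 1241 lower, each with a lone library in a group, and on log2(TPM + 1) values limma called 423 higher and 420 lower. At 51 h there were 4624 calls by edgeR, 2307 higher and 2317 lower. Locus_1065 was then at 106 ± 21.6 against 5.21 ± 0.547 CPM (4.34, SE 0.25, edgeR adjusted p = 6.16e-15). Locus_18679 was at 5591 ± 629 against 828 ± 782 CPM (2.76, SE 0.81, edgeR adjusted p = 0.0116) and at 51.4 CPM in glutamate 51 h replicate 3, a library that stood apart. Without the 3 such libraries its log2 fold change was 2.22 and it was still called. Locus_18679 is also 1 of the 66 loci, described further on, that were at least 8-fold lower in nitrate 3 h replicate 2 than in the other libraries of its group. Locus_11884 was at 5.28 ± 1.64 against 80.6 ± 26.9 CPM (-3.89, SE 0.26, edgeR adjusted p = 1.86e-13), and Locus_253 at 6.22 ± 2.27 against 69.7 ± 22.7 CPM (-3.49, SE 0.34, edgeR adjusted p = 2.51e-09). The count at 51 h was 1752 without glutamine 51 h replicate 3 and 2818 without glutamate 51 h replicate 2. On log2(TPM + 1) values limma called 65 higher and 5579 lower at 51 h, with the median of all loci moved from -0.06 to -0.78.

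Time courses from 3 to 51 h separated the media. In nitrate 327 loci rose and 430 fell. Locus_16559 rose from 3.07 ± 1.16 to 185 ± 74.7 CPM (n = 3; log2 fold change 5.82, SE 0.36, edgeR adjusted p = 2.45e-14) and Locus_1717 from 24.2 ± 9.46 to 609 ± 163 CPM (4.64, SE 0.30, edgeR adjusted p = 4.83e-14). Locus_11442 fell from 21.6 ± 9.37 to 1.502 ± 0.335 CPM (-3.91, SE 0.53, edgeR adjusted p = 4.62e-06) and Locus_17026 from 18.1 ± 6.18 to 1.97 ± 0.309 CPM (-3.26, SE 0.29, edgeR adjusted p = 3.47e-10). Of the 3541 loci that rose by 27 h without nitrogen, 3384 were not called over time in nitrate, 34 were called higher, where 65.9 would be in independent lists, and the rest lower, where 86.7 would be. Of the 3358 loci that fell, 3067 were not called, 168 were called higher, where 62.5 would be, and the rest lower, where 82.2 would be. With replicate as a block the nitrate time course had 1143 calls (497 higher and 646 lower), and it had 476 without nitrate 3 h replicate 1, 453 without nitrate 51 h replicate 1 and 445 without nitrate 51 h replicate 3. Without the 3 libraries that stood apart 408 loci rose and 291 fell, and limma on log2(TPM + 1) gave 16 higher and 23 lower. A fit of these 6 libraries alone gave 95 higher and 85 lower.

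Without nitrogen 2659 loci rose and 2961 fell from 3 to 51 h, and in glutamate 3469 rose and 3346 fell. The same loci had the largest fitted changes in both media among loci that met the naming rule. Locus_253 rose from 0.964 ± 0.893 to 87.9 ± 24.9 CPM without nitrogen (n = 3; log2 fold change 6.30, SE 0.40, edgeR adjusted p = 1.84e-14) and from 1.68 ± 0.917 to 69.7 ± 22.7 CPM in glutamate (5.51, SE 0.37, edgeR adjusted p = 4.98e-14). Locus_11884 rose from 1.11 ± 0.331 to 69.5 ± 6.16 CPM (6.02, SE 0.30, edgeR adjusted p = 2.54e-17) and from 1.39 ± 0.0975 to 80.6 ± 26.9 CPM (5.86, SE 0.28, edgeR adjusted p = 8.02e-18). Locus_1115 fell from 87.8 ± 15.6 to 4.24 ± 4.24 CPM (-5.14, SE 0.47, edgeR adjusted p = 8.71e-11) and from 91.8 ± 20.9 to 1.55 ± 0.338 CPM (-5.89, SE 0.49, edgeR adjusted p = 6.95e-12). Locus_1065 fell from 151 ± 39.3 to 4.72 ± 1.21 CPM (-5.11, SE 0.26, edgeR adjusted p = 3.93e-17) and from 168 ± 33.8 to 5.21 ± 0.547 CPM (-5.00, SE 0.26, edgeR adjusted p = 3.50e-17). On log2(TPM + 1) values limma called 634 higher and 436 lower without nitrogen, and 4648 higher and 225 lower in glutamate, with the median of all loci in glutamate moved from 0.04 to 0.64.

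In glutamine 1763 loci rose and 2213 fell from 3 to 51 h. Locus_55 rose from 18.1 ± 3.04 to 2064 ± 463 CPM (n = 3; log2 fold change 6.84, SE 0.32, edgeR adjusted p = 1.92e-18) and Locus_12170 from 0.683 ± 0.349 to 80.2 ± 17.4 CPM (6.70, SE 0.33, edgeR adjusted p = 1.24e-17). The rise of Locus_55 started from a low level in glutamine. It was at 214 CPM in the inoculum and, at 3 h, at 382, 476 and 488 CPM in nitrate, no nitrogen and glutamate. At 51 h it was at 229, 1987 and 2458 CPM in these media. Locus_6492 fell from 54.3 ± 14.0 to 2.87 ± 1.95 CPM (-4.06, SE 0.41, edgeR adjusted p = 1.31e-09) and Locus_848 from 50.6 ± 21.1 to 5.22 ± 1.99 CPM (-3.40, SE 0.34, edgeR adjusted p = 7.74e-10). Of the loci that rose by 27 h without nitrogen 912 rose over time in glutamine and 55 fell, and of those that fell 1312 fell and 126 rose. All 3 h libraries of replicates 1 and 2 were in run 1 and all 51 h libraries of replicates 2 and 3 in run 2, so each run held a lone library at 1 of the 2 times of a time course, which is assumed to vary like those of other groups. Within runs 1 and 2 the counts were 135 (87 higher and 48 lower) and 67 (38 higher and 29 lower) in nitrate, 2667 and 3598 without nitrogen, 1196 and 1570 in glutamine and 2159 and 4519 in glutamate. With run as a covariate the counts were 1045 in nitrate, 6066 without nitrogen, 4375 in glutamine and 7060 in glutamate. On log2(TPM + 1) values limma called 180 higher and 227 lower in glutamine.

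Transfer into fresh nitrate medium changed 420 loci upward and 300 downward within 3 h of the inoculum. Locus_11442 rose from 2.23 ± 1.16 to 21.6 ± 9.37 CPM (n = 3; log2 fold change 3.14, SE 0.49, edgeR adjusted p = 6.22e-05) and Locus_17026 from 4.14 ± 1.18 to 18.1 ± 6.18 CPM (2.21, SE 0.27, edgeR adjusted p = 7.95e-07), and both fell again later in nitrate. Locus_11294 fell from 665 ± 215 to 58.5 ± 27.0 CPM (-3.51, SE 0.55, edgeR adjusted p = 6.94e-05) and Locus_3154 from 71.8 ± 24.6 to 7.01 ± 1.54 CPM (-3.40, SE 0.29, edgeR adjusted p = 6.03e-10). These changes were not particular to nitrate: over the 4 media at 3 h Locus_17026 was at 16.4 to 18.5 CPM, Locus_11294 at 54.3 to 68.7 and Locus_3154 at 6.21 to 8.89. Locus_11442 differed by medium, at 9.98 CPM without nitrogen, 4.00 in glutamate and 1.13 in glutamine. The count was 365 without nitrate 3 h replicate 2, 351 without inoculum replicate 1, and 213 higher and 243 lower without the 3 libraries that stood apart. Within run 1 there were 28 higher and 81 lower and within run 2 there were 7 higher and 9 lower, each with a lone library in a group, and Locus_11442 and Locus_11294 did not pass within run 2. A fit of these 6 libraries alone gave 45 higher and 84 lower, and limma on log2(TPM + 1) gave 8 higher and 12 lower.

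The change of each medium difference between 3 and 51 h was tested as an interaction. The difference of no nitrogen from nitrate changed in 3131 loci, upward in 1438 and downward in 1693, and 98.9% of them were called between the media at 51 h. The difference of glutamine from nitrate changed in 814 loci, upward in 432 and downward in 382, of which 95.5% were called at 51 h and 26 loci at 3 h. The median size of the medium difference among these loci was 1.29 on the log2 scale at 51 h and 0.17 at 3 h for no nitrogen, and 1.06 and 0.18 for glutamine, a contrast that follows in part from choosing the loci by this change. Without the 3 libraries that stood apart the glutamine interaction had 421 loci upward and 656 downward. With lone libraries in some groups, the no nitrogen interaction had 350 loci upward and 467 downward within run 1 and 352 and 572 within run 2. The glutamine interaction had 120 upward and 18 downward within run 1 and 87 and 24 within run 2, so its balance of directions was not stable. On log2(TPM + 1) values limma called 213 upward and 50 downward for no nitrogen, and 64 upward and 11 downward for glutamine.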

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

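Except the interactions, their fits on the 12 libraries concerned and the regroupings of the libraries, the tests in this part were chosen after the results were seen. The differences of no nitrogen and of glutamine from nitrate changed between 3 and 51 h in 3131 and 814 loci, by the test of the interaction itself. In fits of the 12 libraries concerned, these interactions gave 2163 and 582 loci. Of 60 regroupings drawn, the real groups included, 2 reached the count in each case, and the highest other regroupings gave 2331 and 2313 loci. These regroupings move libraries across both medium and time, so they test for no difference of any kind and leave open whether chance grouped the libraries into an interaction. The first of the highest put all 3 no nitrogen libraries of 51 h on the same side of the contrast, and the second set all 3 h libraries against all 51 h libraries. A count several times the real one, as in the second, points to a structure of the samples by time.

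The shift of glutamine-fed cells at 51 h followed the loci of nitrogen loss: of the glutamine calls among loci called at 27 h without nitrogen, 1553 of 1563, or 99.4%, went the same way. The tables argue against a swap for, or a mixture of, nitrate and starved samples, which would put every locus at or between the levels of those groups: of the 31 loci low in glutamine at 3 h, 41.9% had all 3 glutamine libraries of 51 h below all nitrate and no nitrogen libraries of that time, against 1.19% expected from chance order. They also argue against sequencing run, since the index difference was at least 0.87 within each run, and against depth, since it was 0.85 after the 6 nitrate and glutamine libraries of 51 h were thinned to 3340457 counts each. A candidate explanation, as a hypothesis found in the same data, is that nitrogen from glutamine was running short in these cultures between 27 and 51 h. A share of RNA from a starved sample, added to RNA at the levels of nitrate at 51 h, is argued against as the whole shift. Loci with a mean of at least 10 CPM that fell at least 4-fold by 27 h needed a larger share than loci that rose as much. This gap was at least 14.6 percentage points in each glutamine library. It held with TMM or RLE factors and with no nitrogen or glutamate as the starved sample. Such a share as part of the shift stays open, as does a share added to levels other than those of nitrate. Culture density and the concentrations left in the medium were not analysed here and also stay open.

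A second pattern is the low level of the 31 loci in glutamine at 3 h, which their mean no longer showed at 27 h. Their level above nitrate at 27 h was not particular to glutamine, since no nitrogen had 15 of the loci called higher than nitrate and 7 lower. A level that stays below nitrate at every time is argued against for the 12 loci called higher in glutamine at 27 h. Of the others 0 were called lower than in nitrate and 19 were not called. Against glutamate at 27 h 10 loci were higher, 8 lower and 13 not called, so a lasting lower level stays open for part of the set. At 51 h the set was low again, with 15 loci lower and 10 higher than in nitrate and 14 lower and 2 higher than in glutamate. The nitrate 3 h library that stood apart does not account for the set, because 24 of the 31 loci were still lower than in both nitrate and glutamate without the 3 libraries that stood apart. Scaling between libraries is argued against with library totals as the only scaling, where the median of all loci was -0.23 on the log2 scale between glutamine and nitrate at 3 h and the set's median was -2.28. A response to glutamine, or to ammonium released from it, may underlie the low level at 3 h and was not tested, since the loci carry no names.

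The third pattern concerns nitrate 3 h replicate 2 and glutamate 51 h replicate 3. There were 66 loci at least 8-fold lower in the first than in the other libraries of its group, among 4319 loci with a mean log2 CPM above 4, and 61 of them passed the same bound in the second, where 0.963 would if independent. This set took 2.92% and 4.14% of the counts there and 13.8% to 22.3% in the other 37 libraries. It also varied among those 37, by less. Its median log2 deviation from the rest of the group was lowest there at -1.76, in glutamate 27 h replicate 3, against -5.79 and -5.43 in the pair. Medium and time are argued against by the other 2 glutamate libraries of 51 h, which had no part in the choice, with at least 15.0%, depth by the lowest share of 13.8% among the 32 libraries with totals between those of the pair, and locus length by a median log2 deviation of 0.0197 in the other loci of like length, against -5.43 for the set. A library preparation that left out a class of RNA, such as transcripts without a poly(A) tail, could give 61 shared loci across different media, times and runs, but which class was not tested, and the set supplied 6 of the 4624 calls of glutamine against glutamate at 51 h and 13 of the 6815 calls of the glutamate time course.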

How the results depend on the processing

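The settings were fixed before the data were examined, except those within a run, those without the 3 libraries that stand apart and all for the starvation index. Under alternatives other than leaving out 1 library, 141 of 200 counts of called loci stayed within 1.5 times and 59 did not. The 141 include every such count for glutamate against no nitrogen, where all these fits gave 0. The measure takes no account of direction. For glutamine against glutamate at 51 h, 65 higher and 5579 lower on log2(TPM + 1) counted as within it, beside 2307 and 2317 from edgeR. For the glutamate time course, 4648 higher and 225 lower did, beside 3469 and 3346. The 46 named results (a locus in a comparison) were chosen for large changes without overlap between the groups. This choice leaves little room for a reversed direction. They kept their direction in all 764 alternative values and passed the threshold in 756. The exceptions were Locus_9995 within run 1 and Locus_55 in glutamine against nitrate at 27 h, the latter under both TPM settings and within both runs, Locus_11442 and Locus_11294 in the transfer within run 2, and Locus_11442 in the nitrate time course, to which DESeq2 gave no adjusted p. The starvation index difference of glutamine from nitrate at 51 h ranged from 0.82 to 1.08. For glutamate against no nitrogen at 27 h 35% of loci simulated with a 2-fold change were recovered, and depth was not set apart from the spread between libraries as the limit. Gene lists were not run, because the IDs carry no names.

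The replicate block gave 1 call for no nitrogen against nitrate at 3 h and 1143 for the nitrate time course, and changed no other call by more than 1.5 times. For glutamine against nitrate at 3 h it gave 47, and 39 without the 3 libraries that stand apart. Run as a covariate gave 1 for no nitrogen against nitrate at 3 h. DESeq2 gave 1 for that comparison and 33 for glutamine against nitrate at 27 h. Fits of the compared libraries alone, which have fewer libraries for the spread, gave 20 and 27 for glutamine against nitrate at 3 and 27 h, 37 for glutamine against glutamate at 3 h, 180 for the nitrate time course and 129 for the transfer. Within run 1 there were 4164 calls for no nitrogen against nitrate at 27 h and 27 for glutamine against nitrate at 3 h, and within run 2 there were 1115 for glutamine against nitrate at 51 h, all from fewer libraries. With a lone library in a group, assumed to vary like the others, runs 1 and 2 in turn gave 1 and 1 for glutamine against nitrate at 27 h, 2221 and 2768 for glutamine against glutamate at 27 h, 135 and 67 for the time course in nitrate, 2667 and 3598 without nitrogen, 1196 and 1570 in glutamine, 2159 and 4519 in glutamate, 109 and 16 for the transfer, and 817 and 924, and 138 and 111, for the interactions of no nitrogen and glutamine. Without the 3 libraries that stand apart the transfer had 456. RLE factors and the missing filter moved no count by more than 1.5 times.

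The TPM settings moved most counts. With limma on log2(TPM + 1) and log2(TPM + 0.1) in turn, the calls were 1892 and 1785 for no nitrogen against nitrate at 27 h, 2151 and 1946 at 51 h, 22 and 22 for glutamine against nitrate at 3 h, 1 and 2 at 27 h, 180 and 168 at 51 h, 20 and 28 for glutamine against glutamate at 3 h, 843 and 764 at 27 h, 39 and 36 for the nitrate time course, 1070 and 944 without nitrogen, 407 and 408 in glutamine, 20 and 15 for the transfer, 263 and 222 for the no nitrogen interaction and 75 and 80 for that of glutamine. In glutamate the time course had 3791 with the smaller pseudocount. TPM sums to a fixed total, and with log2(TPM + 1) the median of all loci was 0.51 for glutamate against no nitrogen at 51 h, against 0.03 from edgeR. Except where fewer libraries entered, the cause of these moves was not tested.

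With 1 library left out at a time, the counts ranged over 0 to 3 for no nitrogen against nitrate at 3 h, 5489 to 6769 at 27 h and 5583 to 7308 at 51 h. For glutamine against nitrate they ranged over 29 to 40 at 3 h, 8 to 15 at 27 h and 1249 to 1585 at 51 h. For glutamate against no nitrogen they were 0 at 3 and 51 h and 0 to 1 at 27 h. For glutamine against glutamate they ranged over 52 to 91, 4061 to 5082 and 1752 to 4918. Time courses gave 445 to 578 in nitrate, 4166 to 5626 without nitrogen, 3163 to 3500 in glutamine and 5411 to 6477 in glutamate. The transfer gave 351 to 759, and the interactions 2315 to 3579 and 612 to 929. Groups left with 2 libraries took the spread of the shared fit.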

Other observations

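Except the regroupings of the libraries and the fits given beside them, the tests in this part were chosen after the results were seen. Few further changes were called after 27 h without nitrogen, whereas many were in glutamine. Between 27 and 51 h edgeR called 94 loci without nitrogen (41 higher, 53 lower) and 42 in glutamate (22 higher, 20 lower), after 4762 and 5558 between 3 and 27 h. In glutamine 1699 loci were called between 3 and 27 h and 1702 between 27 and 51 h (819 higher, 883 lower). In nitrate the numbers were 957 and 68. DESeq2 called 243, 143, 1978 and 98 loci between 27 and 51 h without nitrogen and in glutamate, glutamine and nitrate, and without the 3 libraries that stand apart edgeR called 50, 17, 2151 and 86. Tested directly, the change from 27 to 51 h in glutamine differed from that without nitrogen in 678 loci, from that in glutamate in 701 and from that in nitrate in 311. Of the loci that rose by 27 h without nitrogen 683 rose and 5 fell in glutamine between 27 and 51 h, where independent lists would give 165 and 178, and of those that fell 761 fell and 6 rose, where 169 and 157 would.

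Some loci were called at 51 h in glutamine and not without nitrogen. There were 142 loci called between glutamine and nitrate at 51 h that were called at neither 27 nor 51 h without nitrogen, 70 higher and 72 lower, and 68 of them also differed from no nitrogen at 51 h in the same direction (30 higher, 38 lower). Both comparisons use the same 3 glutamine libraries, so a shared direction is also what chance deviations of those libraries would give, and the number expected from this was not computed. Chosen after their values were seen, from the 2 loci with the largest change in each direction among these with a mean of at least 10 CPM, Locus_2366 was at 143 ± 32.1 CPM in glutamine against 69.5 ± 9.34 in nitrate, 67.2 ± 10.997 without nitrogen and 68.4 ± 16.5 in glutamate (SD, n = 3; log2 fold change against nitrate 1.04, SE 0.19, edgeR adjusted p = 1.87e-04). Locus_363 was at 116 ± 10.3 against 622 ± 6.01, 562 ± 68.4 and 543 ± 59.8 CPM (-2.43, SE 0.26, edgeR adjusted p = 7.10e-09).

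Glutamate and nitrate, a pair outside the planned comparisons, differed in 0 loci at 3 h by edgeR (511 at an unadjusted p under 0.05, and 1 by DESeq2), in 6745 at 27 h and in 7376 at 51 h. Glutamine and no nitrogen differed in 66 loci at 3 h, 65 of them lower in glutamine, in 6048 at 27 h and in 3717 at 51 h.

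The 6 libraries of each comparison between 2 groups can be split in 10 ways, the real groups included, too few for a share under 0.05. In fits of those libraries alone, the real split gave 5845 loci for no nitrogen against nitrate at 27 h and 5632 at 51 h, 20 and 1452 for glutamine against nitrate at 3 and 51 h, and 37, 6139 and 3246 for glutamine against glutamate at 3, 27 and 51 h. It gave 180, 4185, 3911 and 6795 for the time courses in nitrate, no nitrogen, glutamine and glutamate, and 129 for the transfer. In each of these 1 of the 10 splits, the real split, reached the count, and the highest other split gave 0. For no nitrogen against nitrate at 3 h and glutamate against no nitrogen at 3, 27 and 51 h all 10 splits gave 0. For glutamine against nitrate at 27 h the real split gave 27 loci and 2 of the 10 splits reached that, the other with 67 loci being the split that follows the sequencing run. There the count was 22 with run as a covariate and 22 with replicate as a block.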
